A study of Homo sapiens with 40 samples.

How the data were processed

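Total RNA of MDA-MB-231 cells was measured on 40 Affymetrix Human Gene 1.0 ST arrays, 4 for each of 10 groups formed by agent, dose, time and lot. Per the labels' protocols, RNA was extracted with a spin column kit, and it was amplified, fragmented and labelled with biotin. Per the submitters' processing notes, the deposited values are log2 signals made with RMA (background correction, quantile normalization and a summary per probe set) in Affymetrix Power Tools 1.10.2, and the submitters tested with limma. Whether the lots were normalized together, and the genome build, are not given in the sources used here. The table held 33297 probe sets with values from 1.2 to 14.52, and all 40 columns were mapped to their samples. The number of arrays limits the precision, and no detection p or count of reads goes with these values.

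Probe sets were named through the platform annotation supplied with the table. Of 33297 probe sets, 19460 had exactly 1 gene symbol, 1754 had several and 12083 were not listed there, so that they stayed unnamed. Of the 19460, 19429 matched a gene of the human RefSeq table (assembly GRCh38.p14) by gene number. Only probe sets with 1 symbol were used for genes. For the 769 genes with more than 1 such probe set the one with the highest mean over all arrays was kept, which left 18417 genes. No filter on dim genes was applied.

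The design text states 4 independent replicates per group and that treated and mock-treated cells were paired to remove the day of measurement. The fit therefore had 16 blocks, 1 per lot, time and replicate number, plus the 6 treated effects, over all 40 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 18 residual degrees of freedom). P values were adjusted by Benjamini-Hochberg over 18417 genes with a threshold of 0.05, two-sided. The 6 comparisons of treated with control cells were joined by 6 contrasts: the agents against each other at 12 h and 24 h, and differences of effects between times and doses. All 48 h and 100 µM arrays belong to lot II and the other treated arrays to lot I. The pairing was checked by correlating the deviations of same-numbered arrays from their group means. In lot I every pair of treated and control arrays had r of at least 0.17, up to 0.60. In lot II r lay between −0.30 and 0.55 at 48 h, with 2 of 4 pairs above 0.1, and between −0.09 and 0.26 at 100 µM, with 1 of 4, so that there the pairing rests on the design text alone.

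Lists of 29 gene groups were fixed beforehand, with 603 of 663 entries measured: cholesterol synthesis, sterol uptake and feedback, LXR targets, prenylation and polyprenyl synthesis, Ras, Rab and Rap GTPases, Kruppel-like factors, SRF and actin genes, YAP and TAZ targets, G1/S genes, G2/M genes, CDK inhibitors and p53 targets, stress response genes, cytokine and NF-kB genes, interferon-stimulated genes, AP-1 and immediate early genes, invasion genes, adhesion genes, matrix and TGF-beta genes, BCL2 family and caspase genes, hypoxia and glycolysis genes, NRF2 and oxidative stress genes, autophagy and lysosome genes, histones, ribosomal proteins, respiratory chain genes, luminal markers, blood cell markers, and fibroblast and endothelial markers. A further list was tested among the 29 but not reported here. Each list was tested with camera (preset correlation 0.01) in each of the 6 comparisons, adjusted over 174 tests, and again with an estimated correlation and with fry. The 12 tests of the 2 lists added later were adjusted together with these, over 186, and 0 of the 186 passed with an estimated correlation. Of the 174 tests, 61 passed the threshold with the preset correlation, and 0 of these did with an estimated one. Fry, which sets a list against no change, called 64 of the tests, with 49 in common. Counts of members adjusted over the list alone were made with Benjamini-Hochberg within each list.

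Genes were named in the text by a rule fixed before the data were examined, as were the fit, the lists and most alternatives. The rule takes the 6 largest rises and falls past the threshold that go 1 way in 4 of 4 pairs, up to 4 members of a list with the smallest p, members that did not pass where they speak against their list's name, the 4 largest in each direction of a contrast, and 13 genes in any case, of which 2 are not analysed here. Genes named outside it, those behind counts of 1 to 5 in the closing section, were chosen after their values were seen. Alternatives were no replicate block, a wider block, a random block, only the arrays compared, quantile normalization anew, median centring, removal of the dimmest genes, which left 12278, the mean of a gene's probe sets, an intensity trend, array weights, and each replicate left out. Choices made after seeing the data were lists of snoRNA and histone cluster genes by symbol, camera on differences of effects, fits without the pair of 48 h replicate 2, leaving out each control array when comparing lots, and overlaps of genes with each replicate left out. For Pearson's r of comparisons with shared controls, 100 pairs of unchanged groups were simulated against the same controls, and the 4 pairs of treated and same-replicate control arrays were split in all 6 ways, 2 pairs for each drug.

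The fit was tested on simulated data made from these arrays' means and spread for each of the 6 comparisons. Over the comparisons a log2 change of 0.5 was recovered in 78 to 87% of 100 genes and a change of 1 in 99 to 100%. With 18417 genes tested, 2.7 to 6% of the genes called in a comparison were false calls. A shift of 0.3 in 1 list of 25 genes gave camera an adjusted p of 3.8e-33 in the simulation of fluvastatin at 24 h, and 0 of 28 unshifted lists passed. Genes were drawn independently in that simulation, so it does not test camera's preset correlation on lists whose members vary together. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.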

Results

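RNA levels were measured on 40 arrays in MDA-MB-231, a human triple-negative breast cancer cell line that spreads to bone in animal models. Cells received zoledronate, fluvastatin or only the solvent (mock-treated control), in 10 groups of 4 replicates. Fluvastatin is a statin, which blocks an early step of the mevalonate pathway that makes cholesterol and the lipid anchors of small GTPases. Zoledronate is a bisphosphonate, given against bone loss and bone metastasis, which blocks farnesyl diphosphate synthase (FDPS) further down the same pathway. Lot I held control, 30 µM zoledronate and 2 µM fluvastatin cells at 12 h and at 24 h. Lot II held control and 30 µM zoledronate cells at 48 h, and control and 100 µM zoledronate cells at 24 h. The values covered 18417 named genes, and the median log2 value of an array over all probe sets lay between 6.19 and 6.33. With 4 arrays per group, the number of arrays limits the precision. Fold changes below are treated minus control on the log2 scale, with n = 4 pairs. Their standard error (SE) comes from the fit of all 40 arrays, not from the spread of those 4 pairs alone. A gene rose or fell where limma's adjusted p was under 0.05.

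The first comparison asked how cells respond to 30 µM zoledronate within a day. Neither the drug's target nor the named genes linked to prenylated GTPases passed the threshold at 12 h or 24 h, which does not exclude smaller changes. At 24 h FDPS differed from the control by 0.09 ± 0.10 and RHOB, a small GTPase whose gene is switched on when prenylation fails, by 0.37 ± 0.21 (adjusted p = 1.0 for both). KLF2, a transcription factor that statins induce in other cells, differed by 0.19 ± 0.11 at 24 h and CCN1, a matrix protein gene driven by YAP and TAZ, by −0.03 ± 0.24 (adjusted p = 1.0 for both). By limma, 0 of 18417 genes passed at 12 h, 511 had an unadjusted p under 0.05, and the fit without the replicate block also gave 0 genes. At 24 h limma again gave 0 genes, with 866 at an unadjusted p under 0.05 where chance alone gives 921, and 0 without the block. As a group, the 16 measured cholesterol synthesis genes had a median shift of 0.07 at 24 h, with 0 members risen, 0 fallen and 0 changed adjusted over the list alone. That shift passed camera's preset test (adjusted p = 0.047), with adjusted p = 0.722 with an estimated correlation and 0.0737 without the replicate block. It also missed the threshold without replicate 1 (0.194), replicate 2 (0.0911) or replicate 3 (0.163). Of the 30 Ras, Rab and Rap GTPase genes none passed at 12 h, over all genes or adjusted over the list alone, and their median of 0.06 (adjusted p = 0.00184, adjusted p = 0.398 with an estimated correlation) was 0.04 without replicate 3 (adjusted p = 0.336). The 13 fibroblast and endothelial markers had a median of −0.06 at 24 h, with 0 members risen or fallen and 0 adjusted over the list alone (adjusted p = 0.00963, adjusted p = 0.273 with an estimated correlation). Their list also missed the threshold with the dimmest genes removed (camera, adjusted p = 0.178) and by fry (adjusted p = 0.103).

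**Figure D1:**
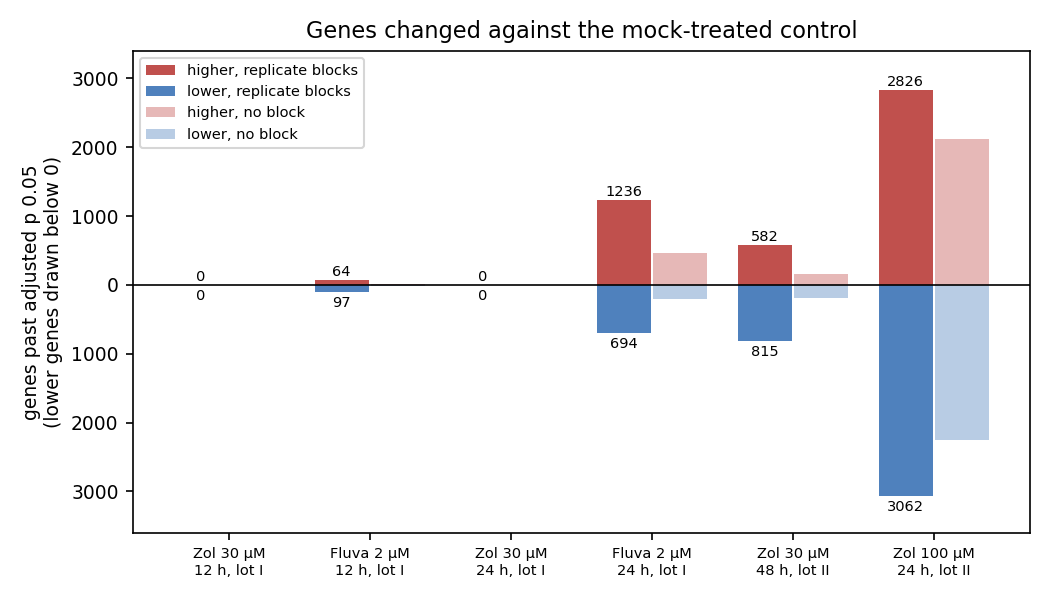
Genes past an adjusted p of 0.05 in each comparison with the mock-treated control, risen genes above 0 and fallen genes below it, with replicate blocks (dark bars, labelled) and without them (pale bars). Counts ran from 0 under 30 µM zoledronate at 12 h and 24 h to 2826 risen and 3062 fallen genes under 100 µM.

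After 12 h of 2 µM fluvastatin, RHOB and 4 of 11 Kruppel-like factors were among the genes that rose. RHOB rose by 1.48 ± 0.21 (adjusted p = 0.0033) in 4 of 4 pairs. CCNA1, a cyclin gene, rose by 1.24 ± 0.22 (adjusted p = 0.012) and TSC22D3, a gene also induced by glucocorticoids, by 0.92 ± 0.14 (adjusted p = 0.0039). CDKN2D, an inhibitor of the G1 cyclin-dependent kinases, rose by 0.56 ± 0.09 (adjusted p = 0.0042), and KLF6 by 0.64 ± 0.10 (adjusted p = 0.0047). Of the 11 Kruppel-like factors, 4 rose, 0 fell and 7 did not pass, and 6 rose adjusted over the list alone. KLF2 was among them at 0.76 ± 0.11 (adjusted p = 0.0033, or 0.055 without the replicate block). The list's median was 0.31 (adjusted p = 9.2e-06, adjusted p = 0.153 with an estimated correlation).

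Among 26 YAP and TAZ targets, genes switched on by stretched, spread cells, 5 fell, 0 rose and 21 did not pass at 12 h of fluvastatin, and 18 fell adjusted over the list alone. TGFB2, a growth factor of that list, fell by 0.82 ± 0.17 on the log2 scale (adjusted p = 0.017, or 0.27 without the replicate block), and the list's median was −0.25 (adjusted p = 5.32e-16, adjusted p = 0.153 with an estimated correlation). CCN1 and CCN2, the classical members, stood at −0.94 ± 0.24 and −0.79 ± 0.20 and did not pass (adjusted p = 0.06 and 0.064). ATP8B1, a lipid flippase gene, fell by 0.72 ± 0.13 (adjusted p = 0.0091). MYC stood at −0.44 ± 0.10 (adjusted p = 0.04, or 0.094 without the block). The 23 SRF and actin genes had 1 fallen and 0 risen member, and 7 fell adjusted over the list alone. Of 16 cholesterol synthesis genes none passed, over all genes or adjusted over the list alone, while their median was 0.14 (adjusted p = 0.00157, adjusted p = 0.467 with an estimated correlation). The 13 prenylation and polyprenyl synthesis genes had a median of −0.05 with 0 passing and 0 adjusted over the list alone (adjusted p = 0.0443, adjusted p = 0.29 with an estimated correlation), and it missed the threshold without replicate 2 (0.142), replicate 3 (0.136) or the block (0.0958). Over all genes, 64 rose and 97 fell (56 and 169 after median centring), 161 together, of which 23 and 14 by 1.5-fold or more. Without replicate 1, 2, 3 or 4 in turn, 0, 18, 37 and 51 genes passed, and 20 passed without the replicate block. All 23 named genes that passed lost their call without replicate 1.

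After 24 h of fluvastatin, AGR2, SPDEF, RHOB and AKR1C1 were among the genes that rose, and DKK1 and MYC among those that fell. AGR2, a chaperone gene of secretory epithelia, rose by 1.86 ± 0.28 (adjusted p = 0.00028). SPDEF, a transcription factor of the same cells, rose by 1.66 ± 0.22 (adjusted p = 8.4e-05). RHOB rose by 1.74 ± 0.21 (adjusted p = 4e-05), and AKR1C1, an aldo-keto reductase that acts on steroids, by 1.85 ± 0.21 (adjusted p = 1.9e-05). A second, dimmer probe set of AKR1C1 stood at only 0.74. AKR1C2 followed at 1.62 ± 0.24, though probes of these near-identical paralogs can share signal. DKK1, a secreted Wnt antagonist that blocks bone formation, fell by 1.01 ± 0.21 on the log2 scale (adjusted p = 0.0035), and MYC fell by 0.66 ± 0.10 (adjusted p = 0.00036). CCN1 fell by 1.03 ± 0.24 (adjusted p = 0.0077), but stood at −0.66 without replicate 1 (adjusted p = 0.15), as CCN2 did at −0.50 (adjusted p = 0.21).

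Of the 16 cholesterol synthesis genes, 9 rose, 0 fell and 7 did not pass at 24 h of fluvastatin, and 10 rose adjusted over the list alone. MSMO1, a sterol oxidase, rose by 0.69 ± 0.13 (adjusted p = 0.0014), while HMGCS1, which makes the first precursor of mevalonate, stood at 0.75 ± 0.16 (adjusted p = 0.0051, or 0.089 without the block and 0.081 without replicate 1). FDPS stayed at 0.05 ± 0.10 (adjusted p = 0.81). The list's median was 0.30 (adjusted p = 1.84e-06, adjusted p = 0.29 with an estimated correlation). Of 16 sterol uptake and feedback genes 6 rose, 0 fell and 10 did not pass, with 7 risen adjusted over the list alone, among them ACSS2 at 0.71 ± 0.09. KLF2 rose by 0.66 ± 0.11 and KLF3 by 0.74 ± 0.12, and 6 of 11 Kruppel-like factors rose, the same number adjusted over the list alone. Of 26 YAP and TAZ targets 16 fell, 0 rose and 10 did not pass, with 18 fallen and 2 risen adjusted over the list alone, and AXL, a receptor kinase of invasive cells, fell by 0.50 ± 0.08. Of 26 interferon-stimulated genes 12 rose and 0 fell, with 14 risen adjusted over the list alone. IFIH1, a sensor of viral RNA, rose by 0.69 ± 0.12, and the list's median was 0.29 (adjusted p = 2.65e-06, adjusted p = 0.153 with an estimated correlation). Of 26 invasion genes 10 rose, 1 fell and 15 did not pass, with 13 and 1 adjusted over the list alone (adjusted p = 2.01e-05, adjusted p = 0.153 with an estimated correlation), and PLAT, the tissue plasminogen activator, rose by 0.92 ± 0.16. Adhesion genes had 8 risen and 1 fallen of 21, with 10 and 1 adjusted over the list alone, and ITGA2, a collagen receptor, rose by 0.79 ± 0.14. Of 27 G1/S genes 7 fell and 0 rose, with 15 fallen adjusted over the list alone, and of 30 G2/M genes none passed, over all genes or adjusted over the list alone. Over all genes 1236 rose and 694 fell (1003 and 1002 after median centring), 1930 together, of which 194 and 49 by 1.5-fold or more. The count was 299 without replicate 1, 1115 without replicate 3, 1102 without replicate 4 and 663 without the replicate block. With the spread taken from these 8 arrays alone it was 2.

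**Figure D2:**
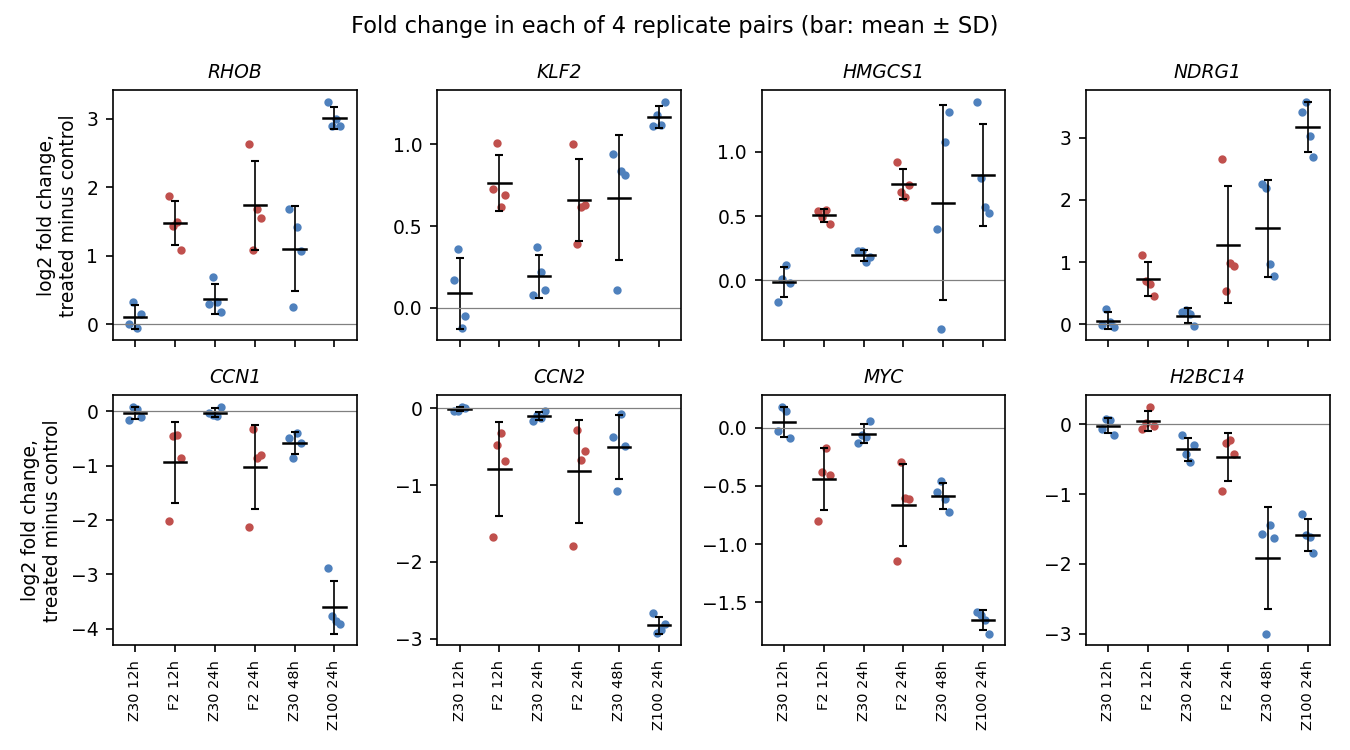
Log2 fold change of 8 genes in each of the 4 replicate pairs (points) of the 6 comparisons, with the mean (line) and SD (bar); blue, zoledronate (Z) at 30 or 100 µM; red, fluvastatin (F) at 2 µM. In the replicate 1 pair fluvastatin moved CCN1 and NDRG1 farthest, and under 100 µM zoledronate all 4 pairs of RHOB, CCN1, CCN2 and MYC lay far from 0.

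Set directly against each other on the same days, 30 µM zoledronate and 2 µM fluvastatin left different RNA levels. At 24 h, zoledronate cells had less RHOB (−1.37 ± 0.21, adjusted p = 0.00065), AGR2 (−1.75 ± 0.28, adjusted p = 0.00086) and SPDEF (−1.56 ± 0.22, adjusted p = 0.00032) than fluvastatin cells. AKR1C1, by its brighter probe set, was lower by the same comparison (−1.62 ± 0.21, adjusted p = 0.00014). DKK1 was higher with zoledronate by 1.03 ± 0.21 (adjusted p = 0.0047, or 0.062 without replicate 1). At 12 h RHOB was already lower with zoledronate (−1.37 ± 0.21, adjusted p = 0.0082), and CD274, the immune checkpoint ligand, was higher by 0.75 ± 0.13 (adjusted p = 0.011). At 12 h 84 genes were higher and 52 lower with zoledronate, 136 together, against 14 without the block and 1, 25, 1 and 53 without replicate 1, 2, 3 or 4. All 9 named genes that passed at 12 h lost their call without replicate 1 and without replicate 3. At 24 h 540 were higher and 792 lower (759 and 633 after median centring), 1332 together, against 367 without the block and 146, 646 and 712 without replicate 1, 3 or 4. With these arrays' own spread 13 genes passed at 12 h and 0 of 1332 at 24 h.

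Under 30 µM zoledronate for 48 h, in lot II, some histone and mitosis genes fell, and some genes induced by low oxygen rose. H2BC14, a core histone gene of the replication-dependent clusters, fell by 1.91 ± 0.17 on the log2 scale (adjusted p = 1.9e-06). SEMA3E, a guidance cue, fell by 1.13 ± 0.11 (adjusted p = 3.9e-06). NDRG1, a stress gene induced by low oxygen, rose by 1.54 ± 0.26 (adjusted p = 0.00099), and ITGA10, a collagen-binding integrin, by 1.52 ± 0.20 (adjusted p = 8.8e-05). RHOB rose by 1.11 ± 0.21 (adjusted p = 0.0026) and KLF2 by 0.67 ± 0.11 (adjusted p = 0.00093), each in 4 of 4 pairs. MMP1, a collagenase, rose by 0.77 ± 0.08 (adjusted p = 5.1e-06), a call that ended without the replicate block (adjusted p = 0.34). CST1, a cystatin, was the largest rise at 1.77 ± 0.29 (adjusted p = 0.00065, or 0.18 without the block). CCN1, at −0.59 ± 0.24, and FDPS, at 0.10 ± 0.10, did not pass (adjusted p = 0.14 and 0.61).

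Of the 13 histone genes listed beforehand, 7 fell, 0 rose and 6 did not pass at 48 h, and 8 fell adjusted over the list alone; their median was −0.46 (adjusted p = 1.09e-09, adjusted p = 0.153 with an estimated correlation), or −0.26 without replicate 2, whose pair lay apart at a mean of −0.79 against −0.30 to −0.27. Of 30 G2/M genes, which drive mitosis, 13 fell, 0 rose and 17 did not pass, and 19 fell adjusted over the list alone. HMMR, a spindle protein, fell by 0.87 ± 0.14, and CCNB1, the mitotic cyclin, fell by 0.54 ± 0.12, or by 0.26 without replicate 2. The list's median was −0.49 (adjusted p = 4.03e-15, adjusted p = 0.326 with an estimated correlation) but only −0.08 without replicate 2. The 27 G1/S genes had 2 fallen and 0 risen members, and 3 fell adjusted over the list alone. Their median of −0.14 (adjusted p = 0.0018, adjusted p = 0.722 with an estimated correlation) turned to 0.11 without replicate 2 (adjusted p = 0.0552) and was −0.26 and −0.32 without replicate 3 or 4. Of 23 hypoxia and glycolysis genes 12 rose, 0 fell and 11 did not pass, with 14 risen adjusted over the list alone. ENO2, a glycolytic enzyme, rose by 0.57 ± 0.10, and the list's median was 0.30 (adjusted p = 4.95e-10, adjusted p = 0.173 with an estimated correlation). YAP and TAZ targets had 7 fallen and 0 risen of 26, with 16 fallen adjusted over the list alone. Among them RBMS3, an RNA-binding protein, fell by 0.78 ± 0.12. Of 24 matrix and TGF-beta genes 4 rose, 2 fell and 18 did not pass, with 6 and 2 adjusted over the list alone, FN1 (fibronectin) rising by 0.66 ± 0.11 and TGFB1 by 0.66 ± 0.08. Of 24 cytokine and NF-kB genes 6 rose and 1 fell, with 10 and 2 adjusted over the list alone. NFKBIA, the NF-kB inhibitor, rose by 0.44 ± 0.08, while IL24, a cytokine that can kill tumour cells, fell by 1.00 ± 0.15. Of 27 stress response genes 2 fell and 0 rose, the same adjusted over the list alone, DDIT3 standing at −0.57 ± 0.19 (adjusted p = 0.068), and the list's median of −0.05 (adjusted p = 0.585) was −0.11 without replicate 2 (adjusted p = 0.00485) and 0.09 without replicate 4 (adjusted p = 0.0447). Over all genes 582 rose and 815 fell (476 and 1114 after median centring), 1397 together, of which 75 and 72 by 1.5-fold or more. The count was 485 without replicate 1, 911 without replicate 3, 349 without the replicate block and 0 with the spread of these 8 arrays alone.

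Zoledronate at 100 µM for 24 h, in lot II, changed the largest number of genes of the 6 comparisons. CCN1 fell by 3.60 ± 0.24 on the log2 scale (adjusted p = 1.7e-10), CCN2 fell by 2.82 ± 0.20 (adjusted p = 5.6e-10) and ANKRD1, another YAP and TAZ target, fell by 2.70 ± 0.20 (adjusted p = 5.9e-10). DKK1 fell by 3.21 ± 0.21 (adjusted p = 1.5e-10) and MYC fell by 1.65 ± 0.10 (adjusted p = 1e-10). RHOB rose by 3.01 ± 0.21 (adjusted p = 3.9e-10), from 8.29 ± 0.19 (SD) in control to 11.31 ± 0.11 (SD) in treated cells. NDRG1 rose by 3.18 ± 0.26 (adjusted p = 3.7e-09), BHLHE40, a repressor induced by low oxygen, by 2.47 ± 0.21 and ITGB4, a laminin receptor, by 2.58 ± 0.21. KLF2 rose by 1.17 ± 0.11 (adjusted p = 3.6e-08) and CDKN1A, the p21 inhibitor of the cell cycle, by 0.51 ± 0.10 (adjusted p = 0.00037). FDPS (−0.08 ± 0.10), DDIT3, a stress response factor (0.01 ± 0.19), and IL6 (0.17 ± 0.11) did not pass, with adjusted p = 0.6, 0.97 and 0.3.

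Of 23 hypoxia and glycolysis genes 19 rose, 1 fell and 3 did not pass under 100 µM, the same adjusted over the list alone, with a median of 0.93 (adjusted p = 1.58e-15, adjusted p = 0.153 with an estimated correlation). P4HA1, a collagen-modifying enzyme, rose by 1.52 ± 0.10 and PDK1, which keeps pyruvate from the mitochondria, by 1.28 ± 0.09. YAP and TAZ targets had 18 fallen and 1 risen of 26, with 20 and 1 adjusted over the list alone, and a median of −0.73 (adjusted p = 1.16e-13, adjusted p = 0.153 with an estimated correlation). Of 27 G1/S genes 23 fell, 0 rose and 4 did not pass, with 25 fallen adjusted over the list alone, and CDC25A, a phosphatase that opens S phase, fell by 1.35 ± 0.18. Of 30 G2/M genes 9 fell and 0 rose, the same adjusted over the list alone, and KIF23, a motor of cell division, fell by 0.73 ± 0.16. CCNB1 stood at −0.35 ± 0.12 (adjusted p = 0.022), a call lost without the block (0.081) and without replicate 2 (0.08), 3 (0.086) or 4 (0.064). Of 13 histone genes 10 fell and 0 rose, the same adjusted over the list alone. Kruppel-like factors had 7 risen and 1 fallen of 11, with 8 and 2 adjusted over the list alone, led by KLF3 at 1.79 ± 0.12. Of 23 SRF and actin genes 11 fell and 2 rose, with 12 and 5 adjusted over the list alone, and CALD1, an actin-binding protein, fell by 1.19 ± 0.08. Of 13 prenylation and polyprenyl genes 6 fell and 2 rose, the same adjusted over the list alone, and RABGGTB, a subunit of the enzyme that prenylates Rab proteins, fell by 0.49 ± 0.06. Cholesterol synthesis genes had 7 risen and 0 fallen of 16, with 8 adjusted over the list alone, HMGCS1 rising by 0.82 ± 0.16. SREBF1, a master regulator of lipid synthesis, rose by 0.63 ± 0.07, and of its 16 uptake and feedback genes 9 rose and 1 fell, the same adjusted over the list alone. Of 22 ribosomal protein genes, a reference list, 6 fell and 0 rose, with 3 fallen adjusted over the list alone. Over all genes 2826 rose and 3062 fell (2339 and 3693 after median centring), 5888 together or 32% of those tested. By 1.5-fold or more 672 rose and 639 fell, and 4380 genes passed without the replicate block.

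**Figure D3:**
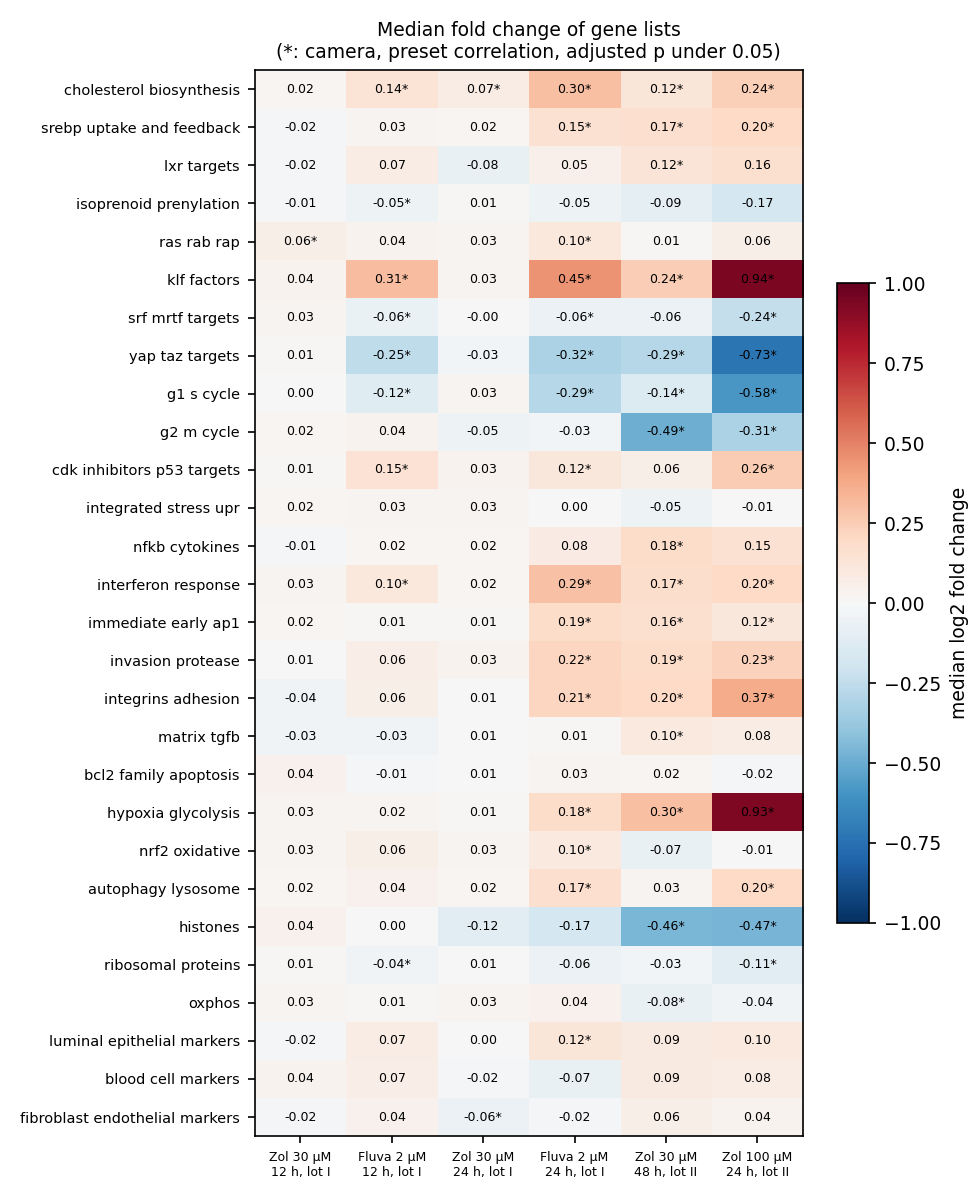
Median log2 fold change of each gene list reported here (cells) in the 6 comparisons with the control (columns); an asterisk marks camera's test with a preset correlation under an adjusted p of 0.05. None of the marked cells passed with an estimated correlation, and hypoxia and Kruppel-like factor genes had the highest medians, 0.93 and 0.94, under 100 µM zoledronate.

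Whether effects changed with time or dose was tested as a difference of fold changes. For fluvastatin between 12 h and 24 h, RHOB moved by 0.26 ± 0.30 (adjusted p = 0.77), and limma gave 0 genes, with 2014 at an unadjusted p under 0.05 and 0 without the block. So the larger count at 24 h was not shown to be a larger effect of any single gene, although 1 gene passed without replicate 2 of the 24 h arrays. For zoledronate at 30 µM between 12 h and 24 h limma gave 0 genes, with 767 at an unadjusted p under 0.05 and 0 without the block. Zoledronate at 48 h and 24 h differed in H2BC14 (−1.55 ± 0.24, adjusted p = 0.008), SEMA3E (−1.10 ± 0.16, adjusted p = 0.0046) and MMP1 (0.75 ± 0.11, adjusted p = 0.0046). These calls and all others of the 75 genes, 22 higher and 53 lower, ended without the replicate block, where 0 passed with 1597 at an unadjusted p under 0.05. The count was 21, 6 and 8 without replicate 2, 3 or 4 of the 24 h arrays and 8, 388, 11 and 168 without replicate 1, 2, 3 or 4 of the 48 h arrays. Between 100 µM and 30 µM at 24 h, the effect was larger at 100 µM for NDRG1 (3.04 ± 0.37, adjusted p = 4e-06) and RHOB (2.64 ± 0.30, adjusted p = 2e-06) and lower for CCN1 (−3.57 ± 0.34, adjusted p = 2.6e-07). There 1694 genes were higher and 2052 lower, 3746 together, and 2065 passed without the block. In both of these last contrasts the lot changes along with the time or the dose, so lot and treatment cannot be told apart.

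Fold changes under the drugs were also compared across genes, which are not independent replicates. Fold changes under fluvastatin at 24 h and 100 µM zoledronate, which share no control arrays, had Pearson's r = 0.70 and Spearman's rho = 0.55 across 18417 genes. RHOB, AGR2 and NDRG1 rose under both drugs and CCN1, DKK1 and MYC fell under both, although CCN1 and NDRG1 missed the threshold under fluvastatin without replicate 1 (adjusted p = 0.15 and 0.065). In all, 1626 genes passed in both in one direction against 305 for independent lists, and 3 in opposite directions; without fluvastatin replicate 1, 3 or 4 the genes in one direction were 279, 982 and 1004, against 46.9, 175 and 174. Zoledronate at 48 h and at 100 µM had r = 0.65 (rho = 0.54), with 1157 genes passing in one direction in both against 225 for independent lists and 4 in opposite directions. These were 405 against 78 without 48 h replicate 1 and 766 against 146 without replicate 3, with 18 in opposite directions without replicate 2. Fluvastatin at 24 h and zoledronate at 48 h had r = 0.45 (rho = 0.29), with 556 genes against 69.8, or 173 against 10.4 without fluvastatin replicate 1 and 231 against 24.3 without 48 h replicate 1. Fluvastatin at 12 h and 24 h had r = 0.41 (rho = 0.28), with 111 genes against 7.95. By limma that overlap was 0, 16, 30 and 39 genes without 12 h replicate 1, 2, 3 or 4 (r = 0.32, 0.48, 0.37 and 0.35), and 53 without 24 h replicate 1. The 30 µM zoledronate and fluvastatin effects of lot I rest on the same 4 controls, which alone raise a correlation. At 12 h r was 0.373 against 0.501 in simulated unchanged groups, and −0.006 with 2 pairs of treated and control arrays for each drug. At 24 h it was 0.432 against 0.499, and 0.135 with 2 pairs for each drug, and the covariance lay 0.0036 above the simulated one at 24 h and −0.000316 from it at 12 h.

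**Figure D4:**
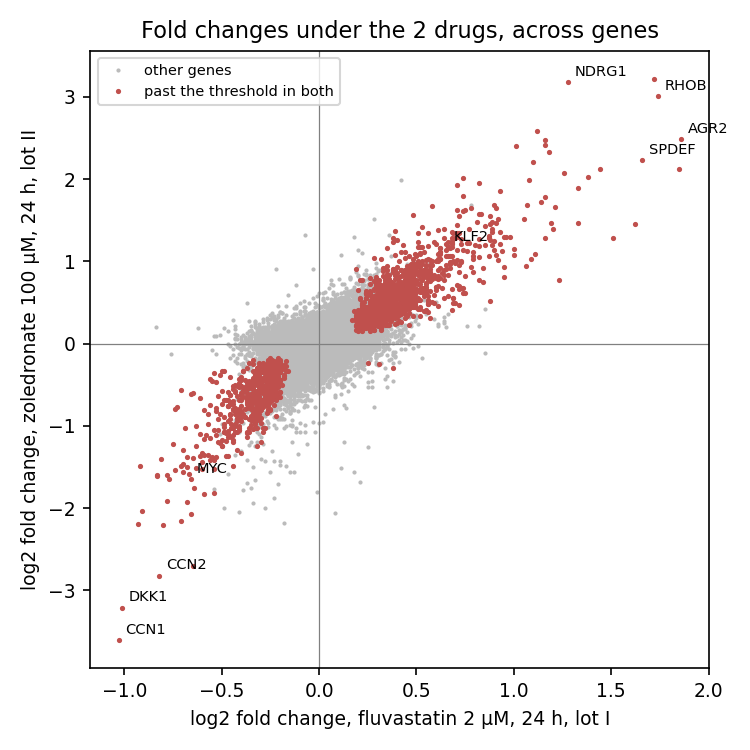
Log2 fold change of each named gene under 100 µM zoledronate at 24 h (y axis) against that under 2 µM fluvastatin at 24 h (x axis); red, genes past the threshold in both. Of these, 1626 lay in 1 direction and 3 in opposite directions.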

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

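The tests of fewer cycling cells, of low power and of the lots, camera on differences of effects, the histone cluster list, the family of 186 list tests and the fits without 1 pair of arrays were chosen only after the result was seen.

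Histone genes stood out in the cells treated with 30 µM zoledronate for 48 h, because 1 of the 4 pairs lay far below the others. The mean of the 13 listed histones was −0.79 in pair 2 and between −0.30 and −0.27 in the other pairs. By symbol, 34 of 58 histone cluster genes fell and 0 rose (26 without the replicate block, 25 without replicate 2), with a median of −0.50 that was −0.32 without replicate 2 and an adjusted p = 8.61e-29 over all 186 list tests (adjusted p = 0.126 with an estimated correlation). Signal shared within a single histone family alone is argued against, since 4 of 5 families had medians below 0 with intervals that exclude 0, from −0.27 for H4 to −0.64 for H2A. Those intervals treat the genes of a family as independent and hold no spread between pairs. Signal shared within each of several families therefore stays open. The histone median lay at percentile 0 of 10000 lists matched on signal (−0.09 to 0.10), which decides nothing about compression of dim probe sets, since that draws fold changes towards 0. Fewer cycling cells may explain the fall, but this stays open, since the G1/S list's median of −0.14 turned to 0.114 without replicate 2, the G2/M list's of −0.49 to −0.08, and neither cell cycle list passed with an estimated correlation. As a group the controls do not carry the fall, with 0 histone genes differing between 48 h and 24 h in lot II. In pair 2, however, both arrays lay apart in the mean log2 value of the histone cluster genes. The control was the highest at 7.33 against 7.13 to 7.21, and the treated array the lowest at 6.35 against 6.78 to 6.87. Zoledronate at 30 µM for 48 h was also measured in 1 lot alone.

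The array of replicate 2 at 48 h of zoledronate correlated with its group at r = 0.9865 across genes, against 0.9943 to 0.9955 for the others. In that pair the LXR targets had a mean fold change of −0.01 against 0.19 to 0.22, the NRF2 genes −0.08 against 0.01 to 0.02 and the ribosomal proteins 0.15 against −0.11 to −0.10. Fluvastatin at 24 h shifted the adhesion genes by 0.51 in pair 1 against 0.13 to 0.16 and the autophagy genes by 0.25 against 0.09 to 0.11, and the LXR targets by 0.04 in pair 2 against 0.16 to 0.18. Under 100 µM zoledronate the LXR targets were at 0.06 in pair 4 against 0.23 to 0.24, and the matrix genes at 0.12 in pair 2 against 0.01 to 0.03. Under 30 µM at 24 h the CDK inhibitors and p53 targets were at 0.08 in pair 3 against 0 in the others. Such lone values occur by chance in about 1 of 20 groups: 1 of 10 groups of arrays and 10 of 174 groups of list means had one, where 8.7 would by chance. They were not spread evenly. The lone array and the lone LXR, NRF2, histone and ribosomal protein means at 48 h all belong to pair 2. List means of the same pair are not independent, so the rate over all groups does not speak for that pair.

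The absence of calls under 30 µM zoledronate at 24 h, against 3746 genes whose effect differed from that at 100 µM, was weighed as well. Low power stays open: with the same controls and blocks fluvastatin gave 1930 genes, but 299, 1115 and 1102 without replicate 1, 3 or 4, 663 without the replicate block and 2 with these arrays' own spread, and the count of another drug does not measure the power for a small effect. In simulated data for this comparison 79% of genes changed by 0.5 and 100% of those changed by 1 were recovered. That share depends on how many genes were made to change and on each gene's spread. It therefore sets no bound for genes with a wide spread, or where few genes change. A small response along that to 100 µM stays open too: genes risen at 100 µM exceeded those fallen by a mean of 0.026 at 30 µM, above 0 in 4 of 4 pairs, while fry passed for neither set. Under 30 µM at 12 h that difference was −0.005, above 0 in 2 of 4 pairs, and fry passed for neither set. At 48 h the same difference was 0.34 and under fluvastatin at 24 h 0.40, with both sets past fry's threshold in each. The lots cannot be told apart from the dose, as 2894 genes differed between their 24 h controls, 1132 higher and 1762 lower in lot II, with 2029 to 2709 when 1 control array was left out.

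Effects that differed between times or doses by camera's preset test follow as medians over a list, none with an adjusted p under 0.05 with an estimated correlation. Fluvastatin at 24 h exceeded 12 h by 0.12 in cholesterol synthesis, 0.08 in sterol uptake and feedback and 0.08 in Ras, Rab and Rap genes. It did so by 0.11 in cytokine genes, 0.16 in interferon-stimulated genes, 0.12 in AP-1 genes, 0.18 in invasion and in adhesion genes, 0.15 in hypoxia genes, 0.09 in autophagy genes and 0.08 in luminal markers, with −0.14 in G1/S genes. For 30 µM zoledronate 75 genes differed between 48 h and 24 h (0 without the replicate block, and 6 to 388 with 1 replicate left out). Its effect was higher at 48 h by 0.15 in sterol uptake genes, 0.20 in LXR targets, 0.24 in Kruppel-like factors, 0.17 in cytokine genes, 0.16 in interferon-stimulated genes, 0.15 in invasion genes and 0.16 in adhesion genes. It was also higher by 0.10 in matrix genes, 0.27 in hypoxia genes and 0.14 in fibroblast and endothelial markers. Lower at 48 h were prenylation genes (−0.11), YAP and TAZ targets (−0.25), G1/S genes (−0.16), G2/M genes (−0.43), histones (−0.39) and respiratory chain genes (−0.09). Some of these rest largely on 48 h replicate 2. Without it the 48 h effect against the control went from −0.14 to 0.114 in G1/S genes, −0.492 to −0.077 in G2/M genes and −0.455 to −0.258 in histones. At 100 µM the effect exceeded that at 30 µM by 0.22 in sterol uptake genes, 0.97 in Kruppel-like factors, 0.18 in CDK inhibitors and p53 targets, 0.28 in interferon-stimulated genes, 0.11 in AP-1 genes and 0.19 in invasion genes. The difference was 0.38 in adhesion genes, 0.82 in hypoxia genes and 0.17 in autophagy genes, and lower were prenylation genes (−0.17), SRF and actin genes (−0.22), YAP and TAZ targets (−0.74), G1/S genes (−0.67), G2/M genes (−0.27), histones (−0.36) and ribosomal proteins (−0.12).

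Among 13837 probe sets without a single gene name, 2 passed under 30 µM zoledronate at 24 h, 32 under fluvastatin at 24 h, 53 under 30 µM at 48 h and 1370 under 100 µM, of which 929 fell and 441 rose.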

How the results depend on the processing

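Fits without the 48 h replicate 2 pair, control arrays left out of the lot comparison, and overlaps of genes with a replicate left out, were chosen after seeing the data. Of 194 settings of the 12 gene counts, 143 stayed within 1.5 times and 51 did not. The 143 include settings where a count of 0 stayed at 0, which say little about stability. These hold all settings for 30 µM zoledronate at 12 h, at 24 h and between these times. The 5888 genes under 100 µM ranged from 4380 to 7140 over the settings of that count. The replicate block is meant to take the day out of the spread, though in lot II the pairing rests on the design text alone. Without the block 20 genes passed under fluvastatin at 12 h, 663 at 24 h and 349 under zoledronate at 48 h. Between the agents 14 passed at 12 h and 367 at 24 h. Between zoledronate at 48 h and 24 h 0 passed, and between 100 µM and 30 µM 2065. With the spread of the compared arrays alone, these counts were 14 under fluvastatin at 12 h, 2 at 24 h (AKR1C2 and GBP2) and 0 under zoledronate at 48 h. They were 13 and 0 between the agents, 1 between 48 h and 24 h (SEMA3E) and 5688 at 100 µM. That fit has fewer degrees of freedom and a spread of its own, and which of these moved the counts was not tested. Removing the dimmest genes, which leaves 12278 genes to adjust over, gave 281 under fluvastatin at 12 h, 246 between the agents at 12 h and 259 between 48 h and 24 h; an intensity trend gave 292, 265 and 214, and array weights 318, 277 and 651. Between 48 h and 24 h, quantile normalization anew gave 122 genes and median centring 127. A random block gave 4 genes between fluvastatin at 24 h and 12 h (GAS8-AS1, GNG4, LAX1 and MFSD2B). The cause of these moves was not tested beyond what is stated.

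Leaving out 1 replicate at a time, the 48 h pair included, gave 0 to 282 genes under fluvastatin at 12 h, 299 to 2524 at 24 h, 485 to 1672 under zoledronate at 48 h, 1 to 257 and 146 to 1780 between the agents at 12 h and 24 h, 0 to 1 between fluvastatin at 24 h and 12 h (CHRNB4), and 6 to 388 between zoledronate at 48 h and 24 h. The single gene left at 12 h between the agents was RTL3 without replicate 1 and CYP1B1 without replicate 3. Array weights were lowest, at 0.22, in the 48 h replicate 2 pair, followed by 0.33 for fluvastatin replicate 1 at 24 h. At 48 h the G1/S median of −0.14 ranged from −0.318 to 0.114 (without replicate 2), and the stress response median of −0.05 from −0.106 to 0.092 (without replicate 4); the cause was not tested. With 2 of the 4 pairs for each drug, the correlation of zoledronate and fluvastatin effects went from 0.373 to −0.006 at 12 h and from 0.432 to 0.135 at 24 h; the 2 effects then share no control and each rests on fewer arrays, and the cause was not tested.

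No scaling moved the median of all genes by over 0.1, but some moved the split of risen and fallen genes. Median centring gave 56 risen and 169 fallen under fluvastatin at 12 h (64 and 97 before), 1003 and 1002 at 24 h (1236 and 694), 476 and 1114 under zoledronate at 48 h (582 and 815), 759 and 633 between the agents at 24 h (540 and 792), 24 and 103 between 48 h and 24 h (22 and 53) 1339 and 2543 between the doses (1694 and 2052) and 2339 and 3693 under 100 µM (2826 and 3062). Quantile normalization gave 66 and 62 between the agents at 12 h (84 and 52) and 50 and 72 between 48 h and 24 h. Of 372 calls of named genes, 257 remained without the block, 144 with the compared arrays' own spread, 340 with a random block, 357 after quantile normalization, 364 after centring, and 363 with array weights, and none changed sign. Of 61 list calls, 57 remained without the block, 54 after quantile normalization, 55 without the dimmest genes and 0 with an estimated correlation. Dim probe sets near background carry compressed fold changes, which limits small effects in them.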

Other observations

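The snoRNA list and the family of 186 list tests were chosen only after the result was seen; the tests of its causes and the splits of the samples were not.

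Under 100 µM zoledronate, where 32% of all genes passed, some genes of autophagy and of growth arrest rose, while others of the same lists fell. Of 22 autophagy and lysosome genes 11 rose, 3 fell and 8 did not pass, with 14 and 4 adjusted over the list alone (adjusted p = 0.003, adjusted p = 0.326 with an estimated correlation), GABARAPL1, which coats autophagosomes, rising by 0.90 ± 0.09. Of 19 CDK inhibitors and p53 targets 10 rose, 2 fell and 7 did not pass, the same adjusted over the list alone (adjusted p = 0.00617, adjusted p = 0.273 with an estimated correlation). TP53INP1, a stress gene of that list, rose by 1.66 ± 0.21. Of 24 BCL2 family and caspase genes 6 rose and 4 fell, with 6 and 5 adjusted over the list alone. BNIP3, a mitophagy receptor induced by low oxygen, rose by 1.30 ± 0.09, and BCL2L1, which protects from apoptosis, fell by 0.53 ± 0.06. Of 23 AP-1 and immediate early genes 10 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.00745, adjusted p = 0.398 with an estimated correlation), JUND rising by 0.78 ± 0.07.

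Single markers of other cell types rose or fell under 100 µM zoledronate, but none of their 3 lists passed camera (adjusted p = 0.152 for luminal, 0.184 for blood and 0.456 for fibroblast and endothelial markers). There 5888 of all 18417 genes (32%) passed, so some members of most lists would pass whatever the list holds. By fry, which sets a list against no change, the luminal (adjusted p = 0.000703) and blood cell lists (adjusted p = 0.00322) did pass. Under fluvastatin at 24 h 5 of 15 luminal markers rose and 0 fell, the same adjusted over the list alone, with a median of 0.12 (adjusted p = 0.0115, adjusted p = 0.215 with an estimated correlation), which missed the threshold without replicate 2 (0.0552) or the dimmest genes (0.15) and was 0.26 without replicate 4. Under 100 µM zoledronate 6 of 15 luminal markers rose and 1 fell, the same adjusted over the list alone. KRT19, an epithelial keratin, rose by 1.55 ± 0.15, while KRT7 fell by 0.62 ± 0.07 and ESR1, the oestrogen receptor of luminal cells, stood at 0.17 (adjusted p = 0.44). Of 14 blood cell markers 3 rose and 0 fell, the same adjusted over the list alone: LYZ (lysozyme) rose by 1.93 ± 0.18, but PTPRC, present on all leukocytes, stood at −0.05 (adjusted p = 0.76). Of 13 fibroblast and endothelial markers 2 rose and 1 fell, the same adjusted over the list alone, PECAM1 rising by 1.30 ± 0.16 and KDR, the receptor of endothelial growth factor, falling. LXR targets, which carry cholesterol out of cells, had 2 risen and 1 fallen of 8, the same adjusted over the list alone, with NR1H3 itself up by 0.66 ± 0.07. Of 19 NRF2 and oxidative stress genes 3 rose and 4 fell, the same adjusted over the list alone. AKR1C1 rose by 2.12 ± 0.21 there (1.02 by its dimmer probe set) and SRXN1, a redox enzyme, fell by 0.35 ± 0.06. Among 27 respiratory chain genes 5 fell and 1 rose, with 2 and 1 adjusted over the list alone.

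Small nucleolar RNAs, which guide the modification of ribosomal RNA, were lower under 100 µM zoledronate. Of 192 measured snoRNA genes 92 fell and 4 rose, with 95 and 4 adjusted over the list alone, and the median was −0.25 (adjusted p = 1.52e-14 over all 186 list tests, adjusted p = 0.126 with an estimated correlation). That median lay at percentile 0 of 10000 lists matched on signal (−0.03 to 0.08), which decides nothing about compression of dim probe sets, since that draws fold changes towards 0. Lower transcripts of the genes that hold them may contribute: the median of 75 host genes was −0.21 (95% interval −0.30 to −0.13, 41 fallen and 3 risen). Yet the fold changes of 97 snoRNAs and their hosts had r = 0.11 across genes (95% interval −0.04 to 0.26, permutation p = 0.3), or 0.05 without the 2 hosts that hold most of them, which decides neither for the hosts nor for a loss of small RNA during extraction, so these cannot be told apart. Fluvastatin at 12 h gave a median of −0.17 with 4 of 192 fallen and 0 risen, 22 fallen adjusted over the list alone (adjusted p = 3.88e-14, adjusted p = 0.126 with an estimated correlation), and at 24 h −0.105 with 13 fallen and 1 risen, 5 and 0 adjusted over the list alone (adjusted p = 0.00181, adjusted p = 0.452 with an estimated correlation), or −0.03 without replicate 1. Under 30 µM zoledronate none of the 192 passed by limma at 12 h or 24 h, and the median was −0.055 at 12 h (adjusted p = 0.000491, adjusted p = 0.434 with an estimated correlation) and 0.105, in the other direction, at 24 h (adjusted p = 3.97e-10, adjusted p = 0.189 with an estimated correlation). At 48 h it was −0.031, with 4 fallen and 1 risen, and the list did not pass camera (adjusted p = 0.324, adjusted p = 0.853 with an estimated correlation). Untreated cells of lot II also differed, with a mean log2 level of 6.34 ± 0.04 (SD) at 24 h and 5.88 ± 0.10 (SD) at 48 h, against 5.83 ± 0.11 (SD) under 100 µM.

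Other splits of the same 8 profiles into 4 and 4, without blocks, were counted for each of the 12 gene counts. For the difference between the doses the real split gave the most genes (4436 genes, 1 of 35 splits, highest other 0), a share under 0.05. That share is the smallest these splits allow and was not adjusted over the 12 counts. The real split is also that of the lots, so it cannot speak for the dose. Chance cannot be excluded for the difference of zoledronate between 48 h and 24 h (1 gene, 2 of 35, highest other 1). Between 24 h and 12 h the real split gave 0 genes under zoledronate and under fluvastatin (35 of 35, highest other 1 in each). Every split reaches a count of 0, so these 2 decide nothing about chance. Within a lot and time the design pairs the arrays by day, so that only 8 of the 35 splits part all 4 pairs, too few for a share under 0.05; the highest other of these gave 0 genes in every comparison. Among all 35 splits the real one gave 55 genes for fluvastatin at 24 h (1 of 35, highest other 0), 5888 for 100 µM zoledronate (1 of 35, highest other 0) and 8 for the agents at 24 h (1 of 35, highest other 1). For fluvastatin at 12 h it gave 7 (2 of 35, highest other 15) and for the agents at 12 h 8 (2 of 35, highest other 37). In both, the highest split set replicates 1 and 4 of both groups against 2 and 3, as shared days would, and the blocked counts were 161 and 136. For 30 µM zoledronate at 48 h it gave 44 (2 of 35, highest other 95 in a split that follows no pairing). Under 30 µM zoledronate the real split gave 0 genes at 12 h and 24 h (35 of 35 in each), the highest others 542 and 19. The 542 come from replicates 1 and 4 against 2 and 3 in both groups and the 19 from 1 and 2 against 3 and 4, which points to a structure of the samples by day.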
